A study of Equus caballus with 4 samples.

How the data were processed

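RNA from 4 sarcoids and from tumour-distant skin of the same 4 horses was stored in a stabilising solution at -80 °C, and a low-input two-colour kit was used to amplify and label 100 ng of it, per the labels. The sarcoid was labelled with Cy3 and the skin with Cy5 on each array, per the labels, with 0 dye-swapped arrays. The descriptions of 3 samples name embryonic stem cells, against their other labels, and the tissue, dye and horse fields were used. The arrays are Agilent horse arrays with 45220 features, of which 1417 are controls.

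The deposited scanner files hold the spot and local background intensity of each channel on a linear scale, per the file headers. They were made with Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes. Processed intensity values are background-subtracted and dye-normalized, per the file headers. The deposited log10 ratio of Cy5 over Cy3 equals the log10 of the processed signals within 0.001 for 90.8% to 93.5% of the spots of an array. The authors' value table of the series holds the same log10 ratio (largest difference 0), with medians of -0.00621, -0.00796, -0.0191 and 0 for horses 1 to 4; its direction and scale were found by that comparison. Other columns are flags of 0 or 1 per spot, per the file headers.

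The files used here give a median rather than a mean signal per spot, and the median was used where the plan named the mean. Background was corrected with normexp (offset 50) and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as feature non-uniform, feature population or background non-uniform outliers in either channel were left out before the normexp fit. The plan named outlier spots as left out but listed that step after the correction. The order used was settled after the data, and the numbers of calls under several settings, had been seen, and it gives many more calls than the listed order. The reason was the fitted background: on all spots, its SD reached 1394 and 1536 in the channels of horse 3, where median signals were 172 and 220 and single spots had net signals down to -97299 after their local background was subtracted. Without the outlier spots the SD lay between 0.0906 and 1.57 on every array. Counts of targets and the calls of the genes named by rule or as members of small lists are reported in both orders. List tests, cell type medians and comparisons of other probes are given only in the order used.

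Spots of 1 probe were averaged. Probes were kept that were well above background on at least 3 of 4 arrays in the sarcoid channel or on at least 3 of 4 in the skin channel, and a gene was represented by its probe of highest mean intensity. Of the 1204 called targets with 2 or more probes, 9 had a probe of opposite sign. Of 43603 probes, 31502 carry an Ensembl transcript ID that the tables used here do not name. Of 3437 probes with a RefSeq accession, 2332 (67.9%) matched a RefSeq gene table of the horse, giving 1031 symbols; unmatched targets kept the file's accession. The same gene can occur under several accessions. No coordinates are given, since the array design uses another build.

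Each target's 4 log2 ratios were tested against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment; the pairing by horse is inside the ratio. Gene lists (37, fixed before the data were examined) were tested with camera at a preset correlation of 0.01 over genes named through the reference, for the 13 lists with at least 5 measured members; 21 lists had 1 to 4 and 3 had none. Restricting camera to named genes was decided after the data were seen. Of 1024 symbols in the lists 140 were measured. Genes named in the text follow a rule fixed before the data were examined: the 12 largest differences in each direction with an adjusted p under 0.05, the same sign on 4 arrays and a symbol; up to 4 called members of each tested list, or 2 where none passed; and ACTB, GAPDH, TBP, HPRT1, PDGFRA and PDGFRB. Members of the lists with 1 to 4 measured members were added after their values were seen; a few of them are not reported here, but stay in all fits and counts of lists. No size is given for a called gene that was not well above background on any array of a channel.

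On simulated data with the spread of the 19607 real targets, the test recovered 29.0% of 100 targets changed by 1 on the log2 scale and 68.0% of 100 changed by 2, with 3 false calls. The simulated ratios were normal, independent between targets and free of any dye effect, and did not pass through the background fit. The false calls therefore do not measure the error of the reported counts. Alternatives covered the background correction, normalization, filters, outlier spots, probe choice, model, threshold, list test and each horse left out. The arrays share 1 slide and 1 scan date, so no block for these could be fitted.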

Results

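Gene expression was measured in equine sarcoids, locally invasive fibroblastic tumours of horse skin, and in skin of the same animal taken away from the tumour. Each of 4 horses contributed 1 two-colour array, which carried labelled RNA from the sarcoid in the Cy3 channel and labelled RNA from the distant skin in the Cy5 channel, so every log2 ratio is a within-horse difference of sarcoid over skin. Between 67.2% and 80.7% of the probe spots were well above background in a given channel of a given array, and no spot was saturated. All 4 arrays lay on 1 slide and were scanned on 1 day, and 0 arrays had the dyes swapped, so a dye effect specific to a gene is part of every ratio below. Only 5.35% of the probes could be given a gene name, which leaves 791 targets with a gene symbol among the 19607 targets tested. The number of arrays limits the precision of each value.

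The comparison asks how the transcripts of a sarcoid differ from those of skin of the same horse. Of 11 measured matrix proteins of fibroblasts 6 were higher and 2 lower in the sarcoids, the highest being LUM (lumican, a small leucine-rich proteoglycan that binds collagen fibrils), with a log2 ratio of 4.24 ± 1.16 (SD, n = 4) from the highest of its 6 probes, the lowest being at 3.26. Of the few keratinocyte and gland genes measured, 5 were lower, 0 higher and 3 did not pass, and the lower ones included LATH (latherin, the surfactant protein of horse sweat) at -6.33 ± 0.26 and KRT15 (a keratin of basal keratinocytes) at -5.12 ± 0.11. In limma, 1146 targets were higher and 1941 lower in the sarcoids at a Benjamini-Hochberg adjusted p under 0.05, of which 713 and 1287 differed by at least 2-fold. Of the 3087 called targets, 3084 had the same sign in all 4 horses, which a call from 4 ratios largely requires. That share is therefore not separate evidence that the horses agree.

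These counts rest on a step that departs from the order in which the plan listed the processing. Spots that the scanner software marked as outliers, background outliers included, were left out before the background model was fitted; with the model fitted to all spots and the outliers left out afterwards, 93 targets were higher and 147 lower, all 240 of them among the 3087, and 44 of the 50 called genes named by rule or as members of small lists no longer passed. The ones that still passed in that order were LUM, BGN, DSE, LATH, IL1R2 and KRT15, so every other call given below for those genes is lost in it. Without any background correction the counts were 1114 higher and 1934 lower. Agilent's own processed signals as given put 48.2% of the calls on the higher side, against 37.1% here, and centring each array on its median without loess put 18.7% there. Leaving out horse 1 left 389 targets higher and 1077 lower, leaving out horse 2 left 591 and 1173, and leaving out horse 3 left 673 and 1255. Of those 50 genes 30 passed with each horse left out in turn, 20 were lost with at least 1 horse left out and 3 with any of the 4. Sizes moved too: the log2 ratio of 15 of the 50 shrank by over 1.5 times in the listed order, and that of 8 grew by over 1.5 times with Agilent's processed signals.

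Among the genes with a symbol, the 12 with the largest rise were LUM, BGN, COL14A1, SPARC, SERPINF1, VCAM1, SELENOP, TNFAIP6, TBX15, MAB21L1, TIMP1 and DSE. BGN, which encodes the matrix proteoglycan biglycan, rose by a log2 ratio of 3.06 ± 0.61 (SD, n = 4; limma adjusted p = 0.00193). COL14A1, a collagen that associates with fibril surfaces, rose by 3.04 ± 0.98, and SPARC, a collagen-binding matrix protein, by 2.99 ± 1.20. The 6 probes of COL14A1 ranged from 1.27 to 3.04, and the value given is the highest. SERPINF1, which encodes pigment epithelium-derived factor, rose by 2.62 ± 1.05, and VCAM1, an adhesion molecule for leukocytes, by 2.61 ± 0.78. SELENOP (selenoprotein P) rose by 2.43 ± 0.75 and TNFAIP6, a hyaluronan-binding protein, by 2.30 ± 0.36. The transcription factor TBX15 rose by 2.22 ± 0.95, MAB21L1 by 2.20 ± 0.77 (its 5 probes from 1.30 to 2.20, and 1.27 in the listed order of background correction), TIMP1, an inhibitor of matrix metalloproteinases, by 2.14 ± 0.80, and DSE, which epimerizes chondroitin to dermatan sulfate, by 2.09 ± 0.50. Without horses 1, 2 and 3 in turn the limma adjusted p was 0.0652, 0.0507 and 0.0551 for SPARC and 0.055, 0.0505 and 0.0559 for SERPINF1. It was 0.0679 without horse 1 and 0.0672 without horse 4 for TBX15, and 0.051 without horse 3 for TIMP1. In the listed order of background correction the limma adjusted p was 0.0964 for COL14A1, 0.0767 for SPARC, 0.0778 for SERPINF1, 0.0706 for VCAM1 and 0.052 for SELENOP. It was 0.124 for TNFAIP6, 0.0904 for TBX15, 0.122 for MAB21L1 and 0.0722 for TIMP1.

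The 12 with the largest fall were LATH, SPINK9, IL1R2, S100A7, KRT15, CALCB, HSD3B2, SLC5A1, SPINK7, CA6, C14H5orf46 and CYP3A89. The protease inhibitors SPINK9 and SPINK7 had log2 ratios of -5.44 ± 1.01 and -3.59 ± 0.06 (SD, n = 4), and SPINK9 was well above background in the sarcoid channel on only 2 of 4 arrays. IL1R2, the decoy receptor for interleukin 1, was at -5.39 ± 0.54, and S100A7, an antimicrobial protein of keratinocytes, at -5.13 ± 0.36. CALCB, a calcitonin gene-related peptide, was at -4.38 ± 0.15, the steroid enzyme HSD3B2 at -4.32 ± 0.37 and the sodium-glucose cotransporter SLC5A1 at -4.06 ± 0.16. The secreted carbonic anhydrase CA6 was at -3.53 ± 0.36, C14H5orf46 at -3.52 ± 0.46 and CYP3A89, a cytochrome P450, at -3.34 ± 0.56. CYP3A89 and S100A7 belong to gene families whose members can share probe signal. In the listed order of background correction 9 of the 12 did not pass, and the log2 ratios were -3.69 for SPINK9, -2.62 for SLC5A1, -2.22 for SPINK7, -2.16 for CA6, -2.22 for C14H5orf46 and -1.90 for CYP3A89 (limma adjusted p = 0.217, 0.162, 0.205, 0.18, 0.156 and 0.205). The limma adjusted p in that order was 0.0517 for S100A7, 0.0746 for CALCB and 0.0638 for HSD3B2. Among targets without a name, ENSECAT00000014418 was at -9.09 and ENSECAT00000008293 at -8.15, while ENSECAT00000015554 was at 3.52 and ENSECAT00000009309 at 3.35.

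**Figure D1:**
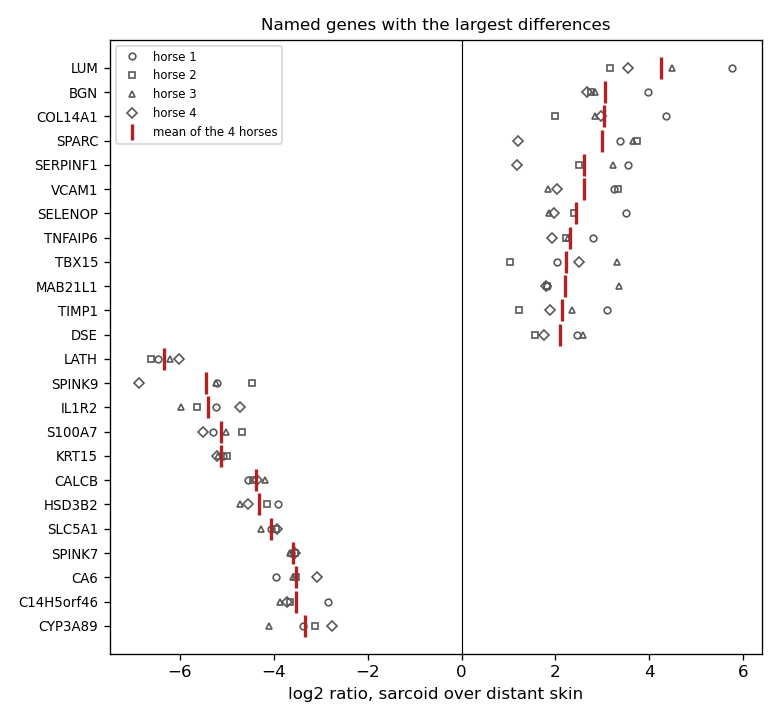
Log2 ratio of sarcoid over distant skin (horizontal axis) for the 12 genes with the largest rise and the 12 with the largest fall. Open symbols are the 4 horses and red bars their mean. All symbols of a gene lie on the same side of 0, which the rule that chose the genes requires. The means run from 4.24 for LUM to -6.33 for LATH.

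Matrix proteins of fibroblasts formed one of the 2 gene lists, of 13 with at least 5 measured members, that camera called with its correlation preset at 0.01. Of 11 measured members, 6 rose, 2 fell and 3 did not pass the test; adjusted over the list alone, 7 rose and 2 fell. Their median log2 ratio was 1.12 (camera adjusted p = 0.00421; adjusted p = 0.993 with an estimated correlation). Beside LUM, BGN, COL14A1 and SPARC, the members that rose were DCN (decorin) at 1.84 ± 0.51 and COL15A1 at 1.04 ± 0.31. COMP, a matrix protein of cartilage and tendon, fell to -2.02 ± 0.88, and HAPLN1, a link protein of hyaluronan, fell but was not well above background on any sarcoid array, so no size is given. DCN, COL15A1, COMP and HAPLN1 were chosen after their values were seen, and whether their calls hold under the alternatives was not examined. The fibrillar collagen list had 1 measured member, COL5A2, which rose by 2.05 ± 0.30 (SD, n = 4); it was at 1.13 in the listed order of background correction and at 3.58 with Agilent's processed signals. All 3 measured genes of fibroblast identity rose: TBX15, VIM (vimentin) by 1.58 ± 0.47, and the growth factor FGF7 by 1.49 ± 0.72. On median centring VIM was at 0.77 (limma adjusted p = 0.104) and FGF7 at 1.20 (limma adjusted p = 0.0607). Without horses 1, 2 and 4 in turn the limma adjusted p of FGF7 was 0.0869, 0.0929 and 0.0767, and that of TBX15 was 0.0679 without horse 1 and 0.0672 without horse 4.

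Interferon-stimulated genes were the other list called. Of 12 measured members 5 rose, none fell and 7 did not pass; adjusted over the list alone, 9 rose and 0 fell. The median was 0.83 (camera adjusted p = 0.00196; adjusted p = 0.993 with an estimated correlation). The chemokine CXCL9 rose by 1.41 ± 0.80, IFI27 by 1.39 ± 0.71, SAMD9 by 1.21 ± 0.31 and the antiviral enzyme OAS1 by 1.01 ± 0.56 (SD, n = 4). Without horses 1 to 4 in turn the limma adjusted p of CXCL9 was 0.0918, 0.0777, 0.0501 and 0.121, and without background correction it was 0.0525. Without horses 1, 2 and 4 in turn it was 0.121, 0.106 and 0.0996 for IFI27 and 0.114, 0.118 and 0.121 for OAS1, and on median centring 0.0903 and 0.16. With Agilent's processed signals CXCL9 was at 3.08 (limma adjusted p = 0.00487). The 2 probes of CXCL9 were at 0.64 and 1.41, and the 3 of SAMD9 ranged from 0.37 to 1.21. None of the immune cell lists that could be tested was called. Of 7 measured macrophage and dendritic cell genes only CSF1R, the receptor for colony stimulating factor 1, passed, with a rise of 1.24 ± 0.51. The log2 ratio was above 0 for 5 of the 7, with a list median of 0.35 (camera adjusted p = 0.169). The limma adjusted p of CSF1R was 0.0674 without horse 2, 0.0502 without horse 3 and 0.0762 on median centring. None of the 6 measured T and NK cell genes passed; KLRD1 was at 0.67 ± 0.36 and CD2 at 0.60 ± 0.65, and the list median was 0.13 (camera adjusted p = 0.487). None of the 5 measured antigen presentation genes passed, and DRA stood at 0.56 ± 1.18 and B2M at -0.35 ± 0.73 (camera adjusted p = 0.937).

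With a correlation estimated from the data camera called 0 lists, and 0 had an unadjusted p under 0.05. With fry, which asks whether the genes of a list move on balance one way, 0 lists passed (lowest adjusted p = 0.0765) and 5 had an unadjusted p under 0.05; its test for change in either direction passed 8 lists, with an adjusted p of 0.00878 for the matrix list and 0.019 for the interferon list. With preranked camera on the limma statistics the adjusted p was 0.0555 for the matrix list and 0.099 for the interferon list. These list tests left the outlier spots out before the background fit, and their values in the listed order are not given here. For the other lists below, the counts adjusted over the list alone equalled those over all genes, except where given.

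Keratinocyte and gland genes were measured too sparsely for a list test. In the basal keratinocyte list KRT15 fell and 1 other member did not pass, and the wound-activated keratinocyte list had 2 measured members, S100A7 and the beta-defensin DEFB4B (-2.59 ± 1.67, limma adjusted p = 0.0501), both lower adjusted over the list alone. The sebaceous list had only HSD3B2, which entered through a gene synonym, since the list as fixed names HSD3B1. It counts among the lower keratinocyte and gland genes given above. The sweat gland list had 3 members, LATH, LTF (lactoferrin), which fell by 2.36 ± 0.79 on the log2 scale, and CA12 at 0.06 ± 0.19. With the channels modelled separately the limma adjusted p of LTF was 0.386 without a replicate block and 0.179 with the spot correlation, and in the listed order LTF was at -1.61 (0.305). No member of the cornified epidermis, hair follicle or adipocyte lists could be tested by name. Of 6 measured melanocyte genes 2 fell and 4 did not pass (camera adjusted p = 0.167). PMEL, a melanosome protein, was at -2.16 ± 0.68, with its 2 probes at -2.16 and -0.99, and at -1.36 in the listed order of background correction. TYRP1, a melanin enzyme, fell (limma adjusted p = 0.00985) but was not well above background on any sarcoid array, so no size is given.

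Camera called none of the signalling lists tested. In the receptor tyrosine kinase and MAPK list, SPRED1 rose by 1.43 ± 0.87 while the receptors MET and FGFR2 were at -3.29 ± 2.01 and -2.98 ± 1.62 (SD, n = 4), both passing the test, and 5 of 8 members did not pass (camera adjusted p = 0.987). Camera's direction for this list was up, while its median was -0.16 and its mean -0.55. The 12 probes of FGFR2 ranged from -2.98 to -0.40 and the 3 of MET from -3.29 to -1.08. Without horses 1, 2 and 3 in turn the limma adjusted p of MET was 0.153, 0.0796 and 0.104, and without the filter on dim probes it was 0.0729. For FGFR2 it was 0.121, 0.0879 and 0.0616 without horses 1, 2 and 4, and 0.0558 without the filter. For SPRED1 it was 0.161, 0.141 and 0.135 without horses 1, 3 and 4, 0.0514 without background correction and 0.088 on median centring. In the TGF-beta and BMP list FST, the activin antagonist follistatin, fell by 3.10 ± 1.18 on the log2 scale and 5 of 6 members did not pass (camera adjusted p = 0.937). IL1RN, the interleukin 1 receptor antagonist, fell by 2.20 ± 0.44 and IL10 rose by 0.51 ± 0.06, while 12 of 14 members of the neutrophil and cytokine list did not pass (camera adjusted p = 0.987). The 8 probes of IL1RN ranged from -2.20 to -0.14, and it was at -1.28 in the listed order of background correction. IL10 was at 0.27 in that order and at 1.16 with Agilent's processed signals, and the limma adjusted p of IL10 was 0.104, 0.132, 0.0898 and 0.0795 without horses 1 to 4 in turn.

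TIMP1 was the only one of 7 measured matrix proteases and inhibitors that passed, and it rose (camera adjusted p of the list = 0.42). The log2 ratio was above 0 for 4 of the 7, and MMP1, at 1.37 ± 1.11, was above 0 in every horse (limma adjusted p = 0.0938). SLC2A1 (glucose transporter 1), which fell by 0.90 ± 0.28, was the only one of 9 hypoxia and glycolysis genes that passed (camera adjusted p = 0.987, median 0.04, mean -0.09). The limma adjusted p of SLC2A1 was 0.076 without horse 1 and 0.0624 without horse 2, and its 2 probes were at -0.90 and -0.21. SLC2A1 was at -0.42 in the listed order of background correction and at -2.35 with Agilent's processed signals. For TIMP1 the limma adjusted p was 0.051 without horse 3 and 0.0577 with separate channels and no replicate block.

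Of the 4 measured immediate early and heat shock genes, FOS, KLF4 and DUSP2 fell, with log2 ratios of -3.10 ± 1.77, -1.19 ± 0.59 and -1.29 ± 0.30, and HSPA8 was at 0.18 ± 0.69. The limma adjusted p of FOS was 0.0876 without horse 1 and 0.113 without horse 2, and that of KLF4 was 0.0878, 0.0775 and 0.0995 without horses 2, 3 and 4. With separate channels and no replicate block it was 0.197 for FOS, 0.0853 for KLF4 and 0.0798 for DUSP2. Both measured erythrocyte genes fell, HBA2 to -1.33 ± 0.33 and HBB to -0.76 ± 0.39, and these are members of a gene family. HBA2 was at -0.73 in the listed order of background correction, and HBB at -2.38 with Agilent's processed signals. HBB was well above background on 1 of 4 sarcoid arrays, and its limma adjusted p was 0.137, 0.0782, 0.0771 and 0.123 without horses 1 to 4 in turn, 0.0532 without background correction and 0.0674 on median centring. Of 4 skeletal muscle genes, MB (myoglobin) fell but was not well above background on any sarcoid array, so no size is given. MYH7 (-0.53 ± 0.56), ACTN3 (0.08 ± 0.25) and PYGM (0.09 ± 0.10) did not pass, and PYGM was well above background on only 1 of 4 sarcoid arrays. Of 3 oxidative phosphorylation genes SDHB fell by 0.83 ± 0.36, and ATP5F1B (-0.37 ± 0.53) and CS (-0.22 ± 0.29) did not pass. FOXC2 fell by 0.61 ± 0.27 (-0.27 in the listed order, -1.37 with Agilent's processed signals), beside VIM in the list of epithelial-mesenchymal transition factors, and TBX15 was the only positional gene measured. Without horses 1, 2 and 3 in turn the limma adjusted p was 0.0855, 0.0606 and 0.0659 for MB and 0.165, 0.145 and 0.128 for FOXC2, which was at 0.0871 on median centring. For SDHB it was 0.0875, 0.0977 and 0.0842 without horses 1, 3 and 4.

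None of the measured members passed in the lists of endothelium (PECAM1 0.41 ± 1.71, VWF -0.06 ± 1.45 and SELE -0.23 ± 0.29), smooth muscle (TAGLN -0.10 ± 0.82), mast cells (TPSB2 -0.54 ± 1.40, FCER1A -1.05 ± 1.49 and KIT -0.01 ± 0.28) or B cells (TNFRSF13C 0.10 ± 0.09). The same held for nerve (PMP22 0.95 ± 0.68), WNT (DKK1 1.04 ± 1.60 and FRZB 0.55 ± 0.38) and hedgehog signalling (GLI1 -0.27 ± 2.06), although adjusted over the list alone 1 nerve gene was higher and 1 lower, and FRZB was higher. Of 51 symbols in the cell cycle and proliferation list only FEN1 (-0.15 ± 0.06) was measured, and it did not pass. Of 26 in the RB and p53 list 2 were measured and neither passed, CCND3 being at -0.11 ± 0.16. So few members cannot show whether proliferation genes differ. No member of the ribosomal protein list (RPLP2 -0.31 ± 0.23, RPSA 0.24 ± 0.44; camera adjusted p = 0.987) or of the reference gene list (camera adjusted p = 0.987) passed, ACTB being at -0.34 ± 0.45 and GAPDH at 0.27 ± 0.48. Without loess, on median centring, GAPDH, RPSA and HSPA8 turned negative, and RPLP2 at -1.18, ACTB at -1.01 and ATP5F1B at -1.04 were called lower (limma adjusted p = 0.0158, 0.0176 and 0.019). TBP, HPRT1, PDGFRA and PDGFRB were not among the targets tested by name.

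**Figure D2:**
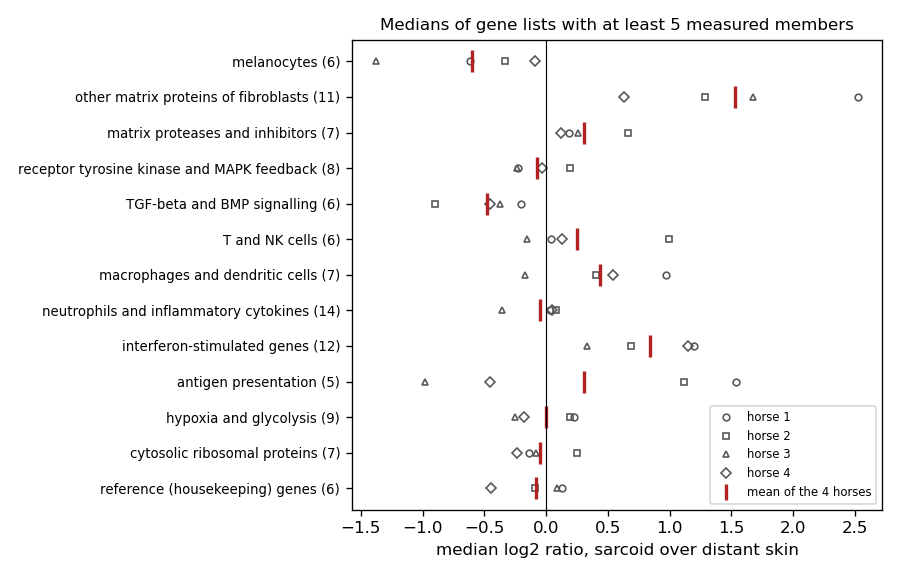
Median log2 ratio of sarcoid over distant skin (horizontal axis) for the 13 gene lists with at least 5 measured members, the number of members in parentheses. Open symbols are the 4 horses and red bars the mean of the 4 medians; the lists of matrix proteins, matrix proteases and interferon-stimulated genes lie above 0 in every horse, those of melanocytes and TGF-beta below 0 in every horse, and antigen presentation runs from -0.98 to 1.54.

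Across targets, Pearson correlations between the log2 ratios of 2 horses ran from 0.621 to 0.743, with a median of 0.662, and Spearman correlations from 0.413 to 0.642, with a median of 0.489; targets are not independent replicates. On 38 probes spotted 5 times, the spots of 1 array differed by a median SD of 0.07 on the log2 scale and the horses by 0.60; over all tested targets the median SD between horses was 0.34.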

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

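The comparisons of cell type medians, the tests on other probes and the count of dye-swapped arrays were chosen after the results they concern had been seen. Of 93 values tested over the 4 horses (80 genes and 13 list medians), 6 had 1 horse far from the others, and chance alone marks about 1 in 20 such groups.

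BGN was at 3.98 in horse 1 against 2.67 to 2.85 in the others, and VIM at 2.29 in horse 1 against 1.32 to 1.39. SPARC was at 1.20 in horse 4 against 3.36 to 3.74. MAB21L1 was at 3.36 in horse 3 against 1.80 to 1.82. IFI27 was at 0.33 in horse 3 against 1.69 to 1.82. The median of the neutrophil and cytokine list was -0.36 in horse 3 against 0.03 to 0.08.

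Of 11 measured matrix genes 6 rose and 2 fell (camera adjusted p = 0.00421; adjusted p = 0.993 with an estimated correlation), and 5 keratinocyte and gland genes fell. A lower share of epithelium and glands alone would raise alike the markers of all cell types not lost with them. The matrix list's median exceeded the pooled median of 34 markers of other cell types by 1.59 ± 0.43 (SE over the 4 horses), from 0.62 to 2.52, which argues against that as the whole cause. The pool holds 6 melanocyte genes, all below 0. These can widen the difference if melanocytes are lost with the epithelium, and the difference was not computed without them. A dye effect of single probes would leave the other probes of these genes near 0. The 26 other probes of 7 called genes had a median of 0.863 times the log2 ratio of the probe used, from 0.417 to 1.24. Overlap between probe sequences was not examined. For COL14A1 the other probes ran from 0.417 to 0.529 times. BGN, DCN, COMP, KRT15, HSD3B2 and LTF had 1 probe each, and for COL14A1 and these genes the question stays open. A dye effect shared by all probes of a gene cannot be told apart from the tissue with 0 dye-swapped arrays, and a change within fibroblasts or in their number may underlie the rest.

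Of 12 measured interferon-stimulated genes 5 rose and 7 did not pass (camera adjusted p = 0.00196; adjusted p = 0.993 with an estimated correlation). Their median exceeded that of 13 T cell, NK cell and macrophage markers by 0.36 ± 0.21 (SE over the 4 horses), from -0.26 in horse 2 to 0.62 in horse 4, so more immune cells in the sarcoid cannot be told apart from a change in other cells. The 8 other probes of 4 called genes had a median of 0.700 times the log2 ratio of the probe used, from 0.307 to 1.02. For OAS1 and EIF2AK2 they ran from 0.689 to 1.02 times, which argues against a dye effect of single probes for these genes. For CXCL9 and SAMD9 they ran from 0.307 to 0.494 times, IFI27 had 1 probe, and for these the question stays open. Overlap between probe sequences was not examined here either. A dye effect shared by all probes of a gene stays open too.

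Turning the sign of some arrays gives 8 splits, counting mirror images as 1, so the share of splits cannot fall under 0.05. The real split called 3087 targets and the highest of the others 0; for differences of at least 2-fold it called 2000 and the highest of the others 0, so that 1 of the 8 splits reached either count. The real split shifted 2 gene lists, while another split shifted 4, and 4 of the 8 splits shifted at least 2.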

How the results depend on the processing

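The order of outlier removal, the use of feature flags only, camera on all tested targets, camera without LOC-named genes and preranked camera were chosen after the data were seen; the other alternatives were fixed before. None of the 50 called genes named by rule or as members of small lists changed direction under any alternative in which it was measured, but many lost their call. Without horses 1, 2, 3 and 4 the number that no longer passed was 17, 16, 13 and 11, so that 20 were lost at least once. It was 9 with separate channels and no replicate block, 8 on median centring, 8 without the filter on dim probes, 7 with a trended and robust prior, 4 without background correction, 3 with separate channels and the spot correlation, and 1 each with Agilent's processed signals as given, the same with loess, the value table and array weights. The log2 ratios of 22 of the 50 moved by over 1.5 times in at least 1 alternative: 15 shrank with outlier spots kept, with the listed order and with feature flags only, 6 shrank with the mean over all probes and 1 (VIM) on median centring. Growth by over 1.5 times was seen for 8 with Agilent's processed signals, with or without loess, and with the value table, and for 1 (HBB) with a normexp offset of 16. Median centring also brought 4 genes past the threshold, RPLP2, ACTB, ATP5F1B and DEFB4B. DEFB4B and KLRD1, which did not pass as reported, passed under several alternatives.

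The counts depended most on which spots entered the background model. With outlier spots left out only after the normexp fit, the order the plan listed, 93 targets were higher and 147 lower (76 and 132 by at least 2-fold), with a median correlation between arrays of 0.596, CA12 at -0.0309 and VWF at 0.1073. With outlier spots kept, the counts were 94 and 147 (77 and 132), the correlation 0.596, CA12 at -0.0308 and VWF at 0.1072. With feature flags only, they were 103 and 155 (84 and 140), the correlation 0.601, CA12 at -0.0302 and VWF at 0.1035. The calls of these settings were all among those reported, and 44, 44 and 43 of the 50 called genes no longer passed. The reported order was settled after these counts had been seen.

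Agilent's processed signals as given made 1887 targets higher, 1601 by at least 2-fold, with KIT at 0.0362; the value table of the series made 1882 and 1598, with KIT at 0.0362. Processed signals with loess gave 1233 higher and 2123 lower by at least 2-fold. Median centring gave 614 higher, 386 by at least 2-fold, and put RPSA at -0.4973, GAPDH at -0.4111, HSPA8 at -0.4967, ACTN3 at -0.0524 and KIT at 0.0628. Scaling between arrays put KIT at 0.0096 and VWF at 0.062, and array weights put KIT at 0.0591, TAGLN at 0.0233 and VWF at 0.2948. A trended and robust prior gave 613 higher. For these the cause was not tested. By construction, every probe on its own gave more calls, 2361 higher and 3795 lower (1468 and 2464 by at least 2-fold), as did an adjusted p under 0.1 (1945 higher) and an unadjusted p under 0.05 (2708 higher and 3434 lower).

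Camera with an estimated correlation, fry and preranked camera shifted 0, 0 and 0 lists; camera on ranks, on all tested targets and without LOC-named genes shifted 2, 2 and 2. Median centring and leaving out horse 3 each shifted 3. Leaving out each horse in turn gave 389 to 820 targets higher and 1077 to 1415 lower, 343 to 627 and 1002 to 1155 by at least 2-fold, and a correlation of 0.63 to 0.717. The lowest counts came without horse 1. Over the same fits ACTN3 ran from -0.0372 to 0.1527, GLI1 from -1.2595 to 0.3124, HSPA8 from -0.1282 to 0.3695, KIT from -0.1424 to 0.0753, PECAM1 from -0.2195 to 1.1588, TAGLN from -0.4469 to 0.1523 and VWF from -0.6043 to 0.5751.

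Signal over background limits the rest: with a probe required above background on all arrays in both channels, 15377 targets were tested and 66 of the 80 named genes measured. A block for slide or scan date could not be fitted, since the arrays share both, and list tests were not run for single probes or for separate channels with the spot correlation.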

Other observations

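No test was run on the values here, which were chosen after they were seen. In the fit of observed on expected log ratios of the spike-in controls, per the file headers, the slopes were 0.799, 0.852, 0.852 and 0.822 for horses 1 to 4. These log ratios are log10 of Cy5 over Cy3, so of skin over sarcoid, unlike the log2 ratios above. The intercepts of that fit were -0.34, -0.194, -0.0659 and -0.334, and its correlations 0.979, 0.979, 0.976 and 0.951.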
